A study of Arabidopsis thaliana with 9 samples.

How the data were processed

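Total RNA of whole seedlings was labelled with biotin and hybridised to 1-colour Affymetrix ATH1 arrays, 1 array per sample, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set and array, made with GCOS and MAS5 per the submitters' processing notes, for which the sources used here give no version. From the values themselves, each array's mean signal after trimming 2% at either end was 99.96, so the authors' signal intensities had been scaled to a common level and were used as deposited. Detection calls, scan dates and probe-level files were not used here. Scaling to a common mean removes any change in total RNA per seedling. MAS5 signals near background scatter widely on a log scale, with 20th percentiles of 8.49 to 9.48 and lowest signals of 0.028 to 0.060. Rises of genes below the 20th percentile in Col-0 replicates 1 and 2 are therefore given against that percentile as a floor. Other dim genes are given without a bound, among them PDF1.2b and AT5G14650, which lay below the 40th percentile in every Col-0 array.

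Samples were grouped by the genotype in the labels, 3 arrays each of Col-0, vtc1-1 and vtc2-1. Signals were log2 transformed with no pseudocount, and a probe set was tested if it exceeded its array's 40th percentile in at least 3 of the 9 arrays and was no control, which left 14603 of 22810. The 3 comparisons were fitted in 1 model of group means over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. Values after ± are standard errors of the limma coefficient for log2 differences and SDs for signals. Principal components were taken of the log2 signals of the tested probe sets. Figures were drawn with matplotlib 3.10.9.

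The procedure was tested on simulated data of the same size, with 14603 probe sets. The simulated noise was independent between probe sets and equal in all groups, with no array apart. In the data the mean variance was 0.260 in Col-0, 0.148 in vtc1-1 and 0.181 in vtc2-1, so the simulated rates need not hold for them. For vtc1-1 against Col-0 limma recovered 46% of 100 probe sets changed 2-fold and 95% of 100 changed 4-fold, with 9 false calls. For vtc2-1 against Col-0 it recovered 58% and 87%, with 11 false calls. The camera test called 20 of 20 raised lists and 1 of 20 unchanged lists in the simulation of vtc1-1 against Col-0. In a raised list every member rose 2-fold. The simulated lists were larger than those tested in the data, which had 7 and 5 tested members, so these counts do not give the power for them.

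Probe sets were named from the platform annotation supplied with the data, with symbols updated through the TAIR10.1 gene table. Of the 22810 probe sets, 13513 have 1 gene symbol, 503 have several and 8794 are not listed there and so stay unnamed, which does not mean that they lack a gene. No coordinates are given, since the files name no genome build. Before the data were examined, 25 gene lists with 429 members were written. Of these members, 63 are paired with a probe set and 53 were tested, so a list's result speaks only for those. The locus code decided a member, except that a symbol which the tables give to another locus only moved it to that locus. This moved 2 members, AATP1 and CNX2, to loci of different proteins than those written. The endoplasmic reticulum folding list had 4 tested members after the move and 5 at the written loci. A list with at least 5 tested members was tested with camera in limma at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, with 1 probe set per gene, the brightest.

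The rule for named genes, set before the data were examined, took VTC1 and VTC2; in each comparison with Col-0 the 8 largest rises and 8 largest falls among probe sets that name 1 gene, had an adjusted p under 0.05, had no overlap between the arrays of both groups and a mean in the higher group above the median of the tested probe sets (4 and 4 between the mutants); up to 4 members of each list with an adjusted p under 0.05, and otherwise none, except that the 4 members of the ascorbate biosynthesis list with the smallest p could be given as values; and the 5 rises and 5 falls shared by both mutants with the largest smaller change. With all arrays this rule named no gene outside the ascorbate list. Therefore 2 further rules were added after the values were seen: the same rule with an unadjusted p under 0.001 in place of the adjusted one, and the same rule in the fit without Col-0 replicate 3. The probe set that was the only call was described as well, without a gene name.

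Unchanged groups were simulated 50 times with the pooled spread to give the overlap and correlation that shared wild-type arrays produce, and the covariance of both sets of fold changes was set against the mean variance of the wild-type arrays divided by their number. Alternatives were quantile normalization, centring on the median, other filters on dim probe sets, a pseudocount or a floor at the 20th percentile, other variance settings, array weights, only the 2 groups compared in the fit, a replicate block, and leaving out each array in turn. Chosen after seeing the data were the omission of Col-0 replicate 3 together with quantile normalization or with the floor, and the lists with the 2 moved members at their written loci.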

Results

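Steady-state transcript levels were measured in whole Arabidopsis thaliana seedlings of 3 genotypes, the wild type Col-0 and 2 mutants with lowered vitamin C (ascorbate), vtc1-1 and vtc2-1. As background, VTC1 encodes GDP-mannose pyrophosphorylase and VTC2 encodes GDP-L-galactose phosphorylase, enzymes of the main plant route to ascorbate. The seedlings had grown for 14 days on agar plates, and total RNA of each sample was hybridised to its own Affymetrix ATH1 array. Each genotype had 3 arrays, 9 in all, and the labels name no batch and do not say whether replicates came from separate sowings, so that p-values measure only the spread between these samples. The deposited signals were scaled alike, with array medians between 43.0 and 45.2, and 14603 of the 22810 probe sets were bright enough to be tested. The number of arrays limits the precision of every value below.

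The wild-type arrays did not lie together. Across the tested probe sets, which are not independent replicates, Col-0 replicates 1 and 2 correlated at r = 0.933. Col-0 replicate 3 correlated at 0.874 and 0.889 with them, at 0.925 to 0.931 with the vtc1-1 arrays and at 0.916 to 0.923 with the vtc2-1 arrays. Among the mutants, vtc2-1 replicate 3 correlated at 0.918 and 0.920 with the other vtc2-1 arrays. On the first principal component, which held 26.8% of the variance, Col-0 replicates 1 and 2 scored -47.5 and -37.4 and Col-0 replicate 3 scored 36.8, beyond all 6 mutant arrays. AT4G12490, a protein of the lipid-transfer type, had a signal of 62.7 and 68.5 in Col-0 replicates 1 and 2 and 1495 in replicate 3. OSM34, an osmotin-like protein, had signals of 51.4, 94.7 and 1489 in the same order. Control transcripts probed at both ends gave a mean log2 ratio of 3' over 5' signal of 0.28 in Col-0 replicate 3, inside the range of 0.20 to 0.65 over the 9 arrays. Other control signals were lowest in that array: 821 for 25S rRNA (1990 to 7015 in the others), 109 for the spiked BioB (127 to 211) and 4861 for the spiked Cre (5491 to 10469), and so was its highest signal of any probe set, at 8681 (10718 to 14435). The exact two-sided permutation test of this ratio gave p = 0.4 for vtc1-1 against Col-0, 0.6 for vtc2-1 against Col-0 and 0.6 between the mutants, where 0.1 is the smallest value that 3 against 3 arrays allow.

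**Figure D1:**
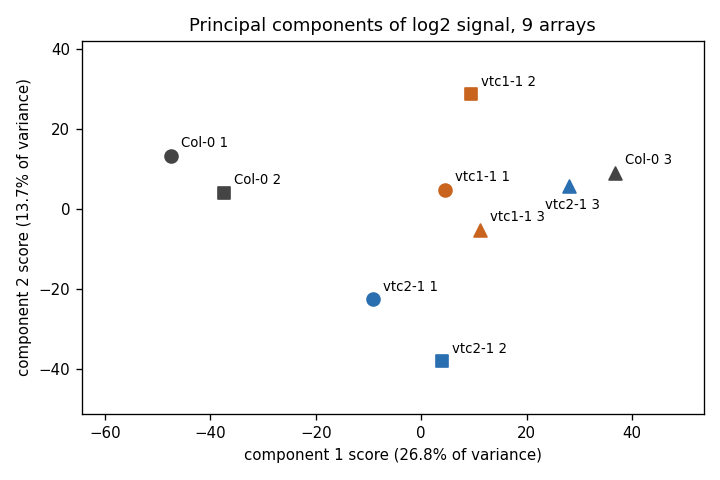
Scores of the 9 arrays on the first and second principal components of log2 signal over the 14603 tested probe sets (no units; colour marks the genotype and shape the replicate). Col-0 replicates 1 and 2 sit at -47.5 and -37.4 on the first component and Col-0 replicate 3 sits at 36.8, to the right of every mutant array.

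The first comparison asked how vtc1-1 seedlings differ from the wild type. No probe set passed the threshold with all 9 arrays, and the genes below are given as values. Among genes that the naming rule took at an unadjusted p under 0.001 the highest was PDF1.2b, a plant defensin. Its signal was 189 ± 171 in vtc1-1 against 15.8 ± 2.82 in Col-0 (SD), a log2 difference of 3.22 ± 0.49 (SE, n = 3 arrays per group, limma adjusted p = 0.296). All 3 Col-0 signals were below their array's 40th percentile, so the size of this difference is uncertain. The probe set of PDF1.2b is of a type that can also detect near-identical defensin transcripts, so the value is uncertain as to the gene. AT3G23550, a transporter of the MATE efflux family, differed by 1.33 ± 0.22 and SCPL45, a serine carboxypeptidase-like protein, by 0.99 ± 0.20. On the lower side stood AT5G05600, a jasmonate-inactivating oxygenase, at -2.30 ± 0.42, AT1G14120 at -2.15 ± 0.43, AT1G76240 at -1.13 ± 0.22 and NAI1, a transcription factor needed for endoplasmic reticulum bodies, at -0.95 ± 0.21. As the naming rule required, the 3 vtc1-1 arrays lay beyond all 3 wild-type arrays in each of these genes. None of the genes reached an adjusted p under 0.05 in limma.

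In this comparison limma called 0 of 14603 probe sets at an adjusted p under 0.05, and 603 had an unadjusted p under 0.05 (330 higher and 273 lower), where 730 would by chance. Without Col-0 replicate 3 limma called 47, of which 33 rose and 14 fell, while the count stayed at 0 without any other array. At 43 of the 47, Col-0 replicate 3 itself lay nearer to the vtc1-1 mean than to the mean of the other wild-type arrays. These 47 were chosen without that array, which favours such a position, and the share over all tested probe sets was not counted.

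The genes that rose in vtc1-1 in that fit, with 2 wild-type arrays, included several with high signals in Col-0 replicate 3 as well. AT4G12490 rose by 3.89 ± 0.53 on the log2 scale (limma adjusted p = 0.0102), from 62.7 and 68.5 in Col-0 replicates 1 and 2 to 874 to 1160 in vtc1-1. AT3G22240 rose by 3.32 ± 0.59, AT1G65500 by 3.80 ± 0.64 and AT1G35710, a leucine-rich repeat receptor kinase, by 3.01 ± 0.50, and PDF1.2b rose by 3.35 ± 0.52. AT1G19960, AT3G18250 and AT1G76960 were below the 20th percentile of signal in Col-0 replicates 1 and 2, and with that percentile as a floor they were at least 16.8-fold, 9.74-fold and 11.6-fold higher in vtc1-1. Of the 14 that fell, the rule for named genes gave AT5G05600 by 2.58 ± 0.44, AT1G76240 by 1.31 ± 0.22, AT1G69160 by 1.17 ± 0.20, AT4G38690 by 1.02 ± 0.18 and AT3G16370 by 0.79 ± 0.13. AT5G05600, PDF1.2b and AT1G76240 also had an unadjusted p under 0.001 with all arrays. Signals of Col-0 replicate 3 were 1495 for AT4G12490, 2927 for AT3G22240 and 418.5 for AT3G18250, each above the vtc1-1 mean of 981, 2640 and 87.5.

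**Figure D2:**
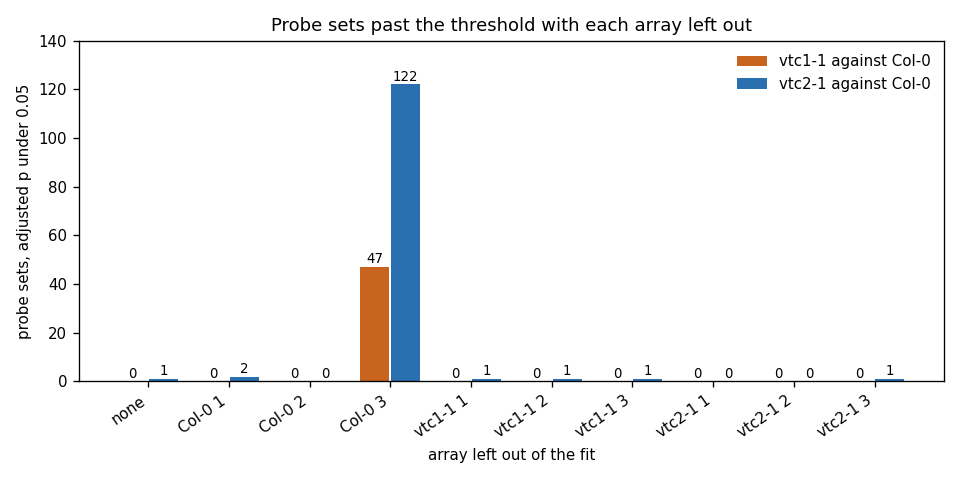
Number of probe sets with an adjusted p under 0.05 in limma (bars, from 0) for vtc1-1 and vtc2-1 against Col-0, with all arrays (none left out) and with each of the 9 arrays left out in turn. The bars reach 47 and 122 without Col-0 replicate 3 and are between 0 and 2 in every other fit.

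The second comparison asked how vtc2-1 seedlings differ from the wild type. A single probe set fell 3.78-fold in vtc2-1, from a signal of 844.8 ± 219.7 in Col-0 to 218.6 ± 23.7 (SD, n = 3 arrays each), a log2 change of -1.92 ± 0.21 (SE; limma adjusted p = 0.00975). The annotation used here pairs it with no gene, so it is called the unnamed probe set below, and its identifier heads the first panel of the figure of single genes. It is described because it was the only one past the threshold. Other genes that the naming rule took at an unadjusted p under 0.001 are given as values, since none passed. The rule left out PDF1.2b, whose mean log2 signal of 6.20 in vtc2-1 was below the median of the tested probe sets. PDF1.2b differed by 2.24 ± 0.49 (limma unadjusted p = 0.00057). On the higher side were AT5G14650 at a log2 difference of 2.70 ± 0.51, AT5G44400 at 1.06 ± 0.25, AT1G28400 at 0.98 ± 0.22, SCPL45 at 0.97 ± 0.20 and AT3G43590 at 0.87 ± 0.20. On the lower side were AT5G26270 at -1.29 ± 0.28, AT1G18740 at -1.21 ± 0.24, EXLA1, an expansin-like protein, at -1.02 ± 0.22, AT1G10020 at -1.02 ± 0.24, SKU5, a cell wall protein of directional root growth, at -0.96 ± 0.21, AT3G44630 at -0.73 ± 0.16 and AT1G61740 at -0.70 ± 0.15.

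Here limma called 1 of 14603 probe sets, and 917 had an unadjusted p under 0.05 (534 higher and 383 lower). When Col-0 replicate 3 was left out limma called 122, of which 80 rose and 42 fell. At 113 of them that array lay nearer to the vtc2-1 mean, a position that choosing them without it favours. The call of the unnamed probe set against Col-0 was lost without Col-0 replicate 2 (limma adjusted p = 0.123), without vtc2-1 replicate 1 (0.0977) or without vtc2-1 replicate 2 (0.134), and also without an intensity trend in the variance (0.129) or with only the 2 groups compared in the fit (0.0783).

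**Figure D3:**
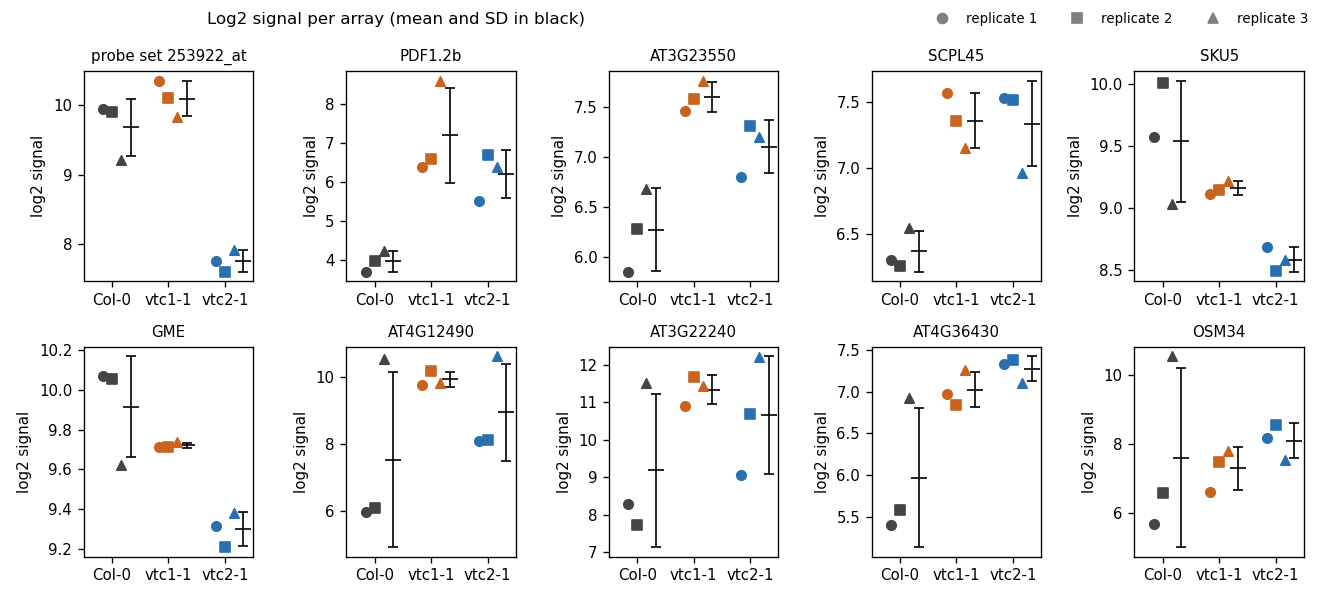
Log2 signal of the unnamed probe set (first panel, under its identifier) and of 9 named genes in each of the 9 arrays (points; shape marks the replicate), with the mean and SD of each genotype in black (n = 3) and a separate vertical scale per panel. The vtc2-1 arrays of the unnamed probe set lie between 7.61 and 7.92, below every other array, and Col-0 replicate 3 of AT4G12490, AT3G22240 and OSM34 lies far above the other Col-0 arrays.

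The 80 probe sets that rose in vtc2-1 without Col-0 replicate 3 included genes that were high in that array. AT4G36430, a peroxidase, rose by 1.79 ± 0.20 on the log2 scale (limma adjusted p = 0.00301), AT4G16260, a beta-1,3-glucanase, by 2.31 ± 0.40, OSM34 by 1.96 ± 0.36 and AT4G12490 by 2.91 ± 0.53. AT2G41090, a calmodulin-like protein, rose by 1.77 ± 0.38, AT2G25510 by 1.86 ± 0.37, and AT1G76960 was at least 12.1-fold higher with the same floor. In 4 of these genes vtc2-1 replicate 3 was above the other vtc2-1 arrays and carried part of the rise, with signals in replicates 1, 2 and 3 of 272, 280 and 1573 for AT4G12490, 41.9, 84.1 and 362.8 for AT1G76960, 644, 1124 and 2541 for AT2G41090 and 2708, 6268 and 9126 for AT2G25510. AT5G14650, which rose by 2.60 ± 0.54, was not high in that array, at a signal of 15.6 there against 13.1 and 27.7 in the other Col-0 arrays. Of those that fell, SKU5 changed by -1.21 ± 0.16, AT5G26270 by -1.61 ± 0.24, AT2G32150 by -1.61 ± 0.33, AT1G52100 by -1.55 ± 0.31, AT1G54740 by -1.39 ± 0.29, AT1G10020 by -1.30 ± 0.20, AT1G68440 by -1.30 ± 0.21 and AT1G32520 by -1.13 ± 0.24. With all arrays OSM34 and AT4G16260 differed by 0.49 ± 0.89 and 0.71 ± 0.97, with Col-0 replicate 3 at signals of 1489 and 513.1, and their sign turned to -0.47 and -0.38 without Col-0 replicate 1 and, for OSM34, to -0.03 without Col-0 replicate 2.

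The mutants were then compared with each other. The unnamed probe set was the only one called by limma, 5.03-fold lower in vtc2-1 than in vtc1-1, where its signal was 1107 ± 195 (SD, n = 3), with a log2 change of -2.33 ± 0.21 (SE; limma adjusted p = 0.00109). All 3 vtc2-1 arrays lay below all 3 vtc1-1 arrays, and the count was 1 whichever array was left out. In all, 527 probe sets had an unadjusted p under 0.05. GME, the GDP-mannose epimerase of ascorbate synthesis, had a signal of 844 ± 8.31 in vtc1-1 and 630.8 ± 37.2 in vtc2-1 (SD, n = 3), a log2 difference of -0.42 ± 0.15 that did not pass the threshold. PYK10, a beta-glucosidase abundant in roots, differed by 0.75 ± 0.25 and passed only when adjusted over the list alone, here the 3 tested root markers.

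The log2 fold changes of both mutants against Col-0 ran together, with a Pearson correlation across probe sets of 0.577 and the same sign at 70.6% of them. Both comparisons used the same 3 wild-type arrays, and unchanged groups simulated against shared controls gave a correlation of 0.497. The covariance was 0.0784, against 0.0547 in the simulation and 0.0866 from the measured spread between the wild-type arrays. No probe set was called by limma in both mutants with all arrays. At an unadjusted p under 0.05, 144 were higher in both (12.1 for independent lists, 79.3 on average and 103 at most in 50 simulations). In the other direction, 66 were lower in both (7.16, 77.8 and 99). These simulations used a pooled spread for all groups, whereas the mean variance was 0.260 in Col-0, 0.148 in vtc1-1 and 0.181 in vtc2-1. Their covariance was below that from the measured wild-type spread. They may thus understate the overlap that shared wild-type arrays give, and 144 against 103 does not show a shared change.

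In the fit without Col-0 replicate 3, 18 probe sets rose and 5 fell in both mutants, against 0.181 and 0.0403 for independent lists. The simulations gave at most 1 and 0. Unchanged groups yield few calls at an adjusted p under 0.05 whatever they share, so these simulated counts are no reference for the overlap. AT1G19960, AT3G18250, AT1G76960, AT3G60420 and AT4G12490 led the rises. In this fit and with the floor, AT3G60420 was at least 6.85-fold higher in vtc1-1 and at least 6.06-fold higher in vtc2-1. Its signal in the omitted Col-0 replicate 3 was 111.1, above the 31.0 to 97.3 of the vtc1-1 arrays. In each of these leading genes vtc2-1 replicate 3 had the highest signal of the vtc2-1 arrays. For AT3G60420 the vtc2-1 signals in replicates 1, 2 and 3 were 18.0, 72.5 and 123.1, and for AT1G19960 they were 24.8, 75.9 and 260.4. The only fall in both that names a single gene was AT1G76240, by 1.31 ± 0.22 in vtc1-1 and 1.08 ± 0.22 in vtc2-1. Part of this overlap may come from the shared wild-type arrays, which were too few to split.

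Ascorbate metabolism was the pathway the genotypes point to. Neither VTC1 nor VTC2 has a probe set paired with it in the annotation used here. Probe sets not listed there could measure these genes, and which gene the unnamed one measures could not be checked. The transcripts of the mutated loci could therefore not be identified, and the labels were not checked by them. In the ascorbate biosynthesis list, 7 of 13 members were tested and none passed over all probe sets. GME in vtc2-1 had a log2 difference of -0.62 ± 0.15 from Col-0, with all 3 vtc2-1 arrays below all 3 Col-0 arrays, and it was the only member past the threshold adjusted over the list alone. It fell by 0.76 ± 0.13 without Col-0 replicate 3 (limma adjusted p = 0.0266). GME in vtc1-1 stood at -0.20 ± 0.15. PMM, a phosphomannomutase, stood at 0.36 ± 0.18 in vtc1-1 and 0.34 ± 0.18 in vtc2-1, and VTC4, an L-galactose 1-phosphate phosphatase, at 0.22 ± 0.21 and 0.35 ± 0.21. Leaving out Col-0 replicate 3 moved the vtc1-1 values to -0.34 ± 0.13 for GME, 0.55 ± 0.15 for PMM and 0.07 ± 0.21 for VTC4. None of these passed the threshold. AT2G04650 stood at -0.45 ± 0.40 in vtc1-1 and AT4G33670 at -0.14 ± 0.15 in vtc2-1.

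The gene lists gave few measurable members. Of 429 members in 25 lists fixed before the data were examined, 53 were tested, and only the ascorbate biosynthesis list and the ascorbate-glutathione cycle (5 of 19 members) had the 5 needed for a set test. Neither was called by camera in limma in any comparison. For the biosynthesis list the adjusted p was 0.542 in vtc1-1 and 0.494 in vtc2-1 (adjusted p = 0.553 and 0.508 with an estimated correlation), and for the cycle it was 0.541 and 0.109. All 5 tested members of the cycle had values above 0 in both mutants, up to 0.27 in vtc1-1 and 0.52 in vtc2-1, and none passed. Over the lists, 2 members passed in vtc1-1 when adjusted over the list alone, PDF1.2b and PDF1.2 of the jasmonate list, and 4 in vtc2-1, GME, CSN5B, PDF1.2b and PYE, a transcription factor of iron deficiency, whereas none passed over all probe sets. These members were named after their values were seen. The jasmonate list had 2 tested members, as had the lists of CSN5B and PYE, so the adjustment within them is slight. The probe set of PDF1.2b can also detect near-identical defensin transcripts, so PDF1.2b and PDF1.2 may not be separate results. The 3 tested reference genes had log2 differences from Col-0 of -0.10 to 0.09 in vtc1-1 and -0.14 to 0.12 in vtc2-1.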

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

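The test of the wrong vtc2-1 label, the test of the shared wild-type arrays and the test of the called probe set against background were chosen after their results were seen.

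The probe set called between the mutants, which has no gene name here, stood out because the direct test between the mutants differed, with a log2 change of -2.33 in vtc2-1 against vtc1-1. It was lower in 3 of 3 vtc2-1 arrays than in any other array. Scaling between arrays is argued against, since the adjusted p of this difference in limma was at most 0.00103 after quantile normalization or median-centring (0.00109 as deposited, and 0.0456 at most over all alternatives). A signal near background is argued against as well, since the lowest vtc2-1 signal was 6.44 times its array's 40th percentile. A difference between the vtc2-1 line and the others, whether through the vtc2 mutation or another change carried by that line or a sequence difference under the probes, stays open as untested. The annotation used here pairs VTC2 with no probe set, so whether this one measures VTC2 itself could not be checked.

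Col-0 replicate 3 lay apart from Col-0 replicates 1 and 2. Scaling between arrays is argued against, since after quantile normalization the SD of its difference from them was still at least 0.742, above the highest value between arrays of a mutant, 0.638. A vtc2-1 sample with a Col-0 label is argued against by the probe set called between the mutants, whose log2 signal in this array was 1.29 above the highest vtc2-1 array. A vtc1-1 sample with a Col-0 label stays open. Of the 100 probe sets with the smallest p between vtc1-1 and Col-0 replicates 1 and 2, the array lay nearer Col-0 at 8%. This was inside the 3% to 18% of vtc1-1 arrays, each left out when its probe sets were chosen. Those sets were chosen with 2 vtc1-1 arrays and the set for the 8% with 3, so the shares are not fully alike. The same measure against vtc2-1 gave 11%, inside 11% to 38%, and so does not single out a genotype. Other values set the array apart from vtc1-1 as well. It scored 36.8 on the first principal component against 4.46 to 11.2 in vtc1-1, lay beyond all vtc1-1 arrays at 26 of the 47 calls made without it, and had signals of 1489 for OSM34 (96.4 to 222.9 in vtc1-1) and 18.7 for PDF1.2b (83.8 to 386.2). These do not exclude the label, since the vtc2-1 arrays spread from -9.19 to 28.0 on that component. Neither gene marked vtc1-1 past the threshold with all arrays, but that fit counted this array as Col-0. In the fit without it PDF1.2b passed (limma adjusted p = 0.0212). So did AT3G23550 (limma adjusted p = 0.0102), with a signal of 102.7 in this array and 175.9 to 216.8 in vtc1-1. At 43 of the 47 calls of that fit, however, the array lay nearer the vtc1-1 mean. A difference in the preparation or hybridisation of this sample stays open and was not tested; its signals of 25S rRNA (821), the spiked BioB (109) and the spiked Cre (4861) were the lowest of the 9 arrays. A difference in the state of the plants, such as growth conditions or stress, could not be tested because the labels give no batch.

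The shared direction of both mutants is a pattern that the shared wild-type arrays could give. With all arrays the covariance of the fold changes differed by -0.00823 from what the spread between the Col-0 arrays produces. Without Col-0 replicate 3 the covariance exceeded that value by 0.0989, but 2 arrays that deviate together would raise it without showing in their own spread. A shared effect of both mutations stays open.

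The calls were also counted over other splits of the arrays. In each comparison 3 against 3 arrays make 10 splits, too few for a share under 0.05. For vtc1-1 against Col-0 the real split called 0 probe sets and the highest other 0, so that 10 of 10 gave as many. For vtc2-1 against Col-0 the real split called 1 and the highest other 101, and 3 of 10 gave as many. The split with 101 calls set Col-0 replicates 1 and 2 with vtc2-1 replicate 1 against the rest, which points to a structure of the samples that the genotypes do not follow. Between the mutants the real split called 1 and the highest other 0, and 1 of 10 gave as many. With the Col-0 arrays against all 6 mutant arrays and the array left out that gave most calls, 161 probe sets were called, and 3 of the 84 choices of 3 arrays, the real one included, gave as many, with 292 as the highest of the others. Each of the 3 held both Col-0 replicates 1 and 2, which had been seen to stand apart, and choices without both gave at most 19. The count therefore restates that this pair stands apart. Of the 7 choices that hold the pair 3 gave as many, too few choices for a share under 0.05.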

How the results depend on the processing

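Col-0 replicate 3 decided the counts against Col-0. Over the fits that left out each array in turn, the probe sets changed ranged from 0 to 47 in vtc1-1 against Col-0, from 0 to 122 in vtc2-1 against Col-0 and from 0 to 23 the same way in both mutants, with each highest value from the fit without Col-0 replicate 3. Of the settings chosen after seeing the data, omission of that array with quantile normalization called 47, 113 and 23, with 46 and 111 probe sets in common with the calls as deposited, and with the floor it called 62, 157 and 33, with 45 and 120 in common. In the 20 other settings the count for vtc1-1 was 0 throughout, and that for vtc2-1 against Col-0 was 0 to 2. For vtc2-1 against Col-0 it was 0 without a variance trend and 0 with only the 2 groups compared in the fit. Between the mutants it was 2 without a variance trend and 1 in the others. The cause of these moves was not tested. None of the lists fixed beforehand was called under any setting. With the written loci of the 2 moved members, the endoplasmic reticulum folding list gained a test and was not called (adjusted p of camera in limma 0.263 in vtc1-1 and 0.238 in vtc2-1). With the replicate block 0, 1 and 1 probe sets were called, and no call changed. The deviations of same-numbered arrays correlated at -0.0744 to 0.199 and those of other arrays at -0.223 to 0.120, so not every same-numbered pair deviated together and the arrays were not treated as paired, although 6 of 9 arrays matched best with their own number, a hint from the data that leaves pairing open. Of the 22 named values not chosen in the fit without Col-0 replicate 3, 6 passed the threshold there that had not passed before. Named values that changed sign were OSM34 in vtc2-1 (-0.47 without Col-0 replicate 1, -0.03 without Col-0 replicate 2 and 1.96 without Col-0 replicate 3) and AT4G16260 in vtc2-1 (-0.38 without Col-0 replicate 1 and 2.31 without Col-0 replicate 3), neither past the threshold with all arrays. Signals near background limit the fold changes of dim genes.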

Other observations

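The list of pathogenesis-related families described here was written after the leading genes had been seen, and its tests and those of plastid transcripts were chosen then.

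Families of pathogenesis-related proteins, which plants make under attack and which include chitinases, thaumatin-like proteins, defensins and lipid-transfer proteins, were set out by family membership as 54 loci, of which 26 were tested. Averaged over these genes, the log2 signal deviated from the mean of all arrays by -0.83 and -0.68 in Col-0 replicates 1 and 2 and by 0.80 in Col-0 replicate 3. The vtc1-1 arrays lay at 0.20, 0.26 and 0.37 and the vtc2-1 arrays at -0.25, -0.24 and 0.38. These averages include genes that prompted the list. The averages were repeated without the 5 members named in the results above (AT4G16260, OSM34, PDF1.2, PDF1.2b and AT4G12490). ChiC and AT2G38870, named below, stayed in. The 3 Col-0 arrays then lay at -0.59, -0.37 and 0.71, the vtc1-1 arrays at 0.21, 0.20 and 0.16 and the vtc2-1 arrays at -0.21, -0.43 and 0.33. Col-0 replicate 1 still lay below all mutant arrays and Col-0 replicate 2 lay above 1 of them. The hypothesis that these families are higher in both mutants than in the wild type did not hold with all arrays, with a camera p in limma of 0.034 in vtc1-1 and 0.730 in vtc2-1 (0.344 and 0.873 with an estimated correlation). In that fit 14 of 26 members were above 0 in vtc1-1 and 12 in vtc2-1, with medians of 0.13 and -0.04. Without Col-0 replicate 3 the p of camera in limma was 1.55e-07 and 7.05e-05 (0.00204 and 0.00674 with an estimated correlation), with 20 of 26 members above 0 in each mutant and medians of 0.77 and 0.66. With those 5 members left out, 21 remained, and the p of camera in limma without that array was 0.00115 and 0.0336 (0.0162 and 0.0674 with an estimated correlation), whereas with all arrays it was 0.455 and 0.417. In the fit without that array, ChiC, a class V chitinase, rose in vtc2-1 (limma adjusted p = 0.0157), and AT2G38870, a protease inhibitor of the PR-6 type, rose by 1.19 in vtc1-1 (limma adjusted p = 0.0441). As the list was written from such genes, these values do not show a shared state of the plants, and they do not settle which wild-type arrays the mutants should be compared with.

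Transcripts encoded in the plastid genome, 69 tested probe sets, had a median log2 difference from Col-0 of -0.11 in vtc1-1, with 16 of 69 above 0, and of -0.0028 in vtc2-1, with 33 of 69 above 0. The p of camera in limma was 0.00117 and 0.951, and with an estimated correlation it was 0.512 and 0.990. In vtc2-1 against vtc1-1 the median was 0.15, with 51 of 69 above 0 and a p of camera in limma of 4.96e-04 (0.483 with an estimated correlation). Without Col-0 replicate 3 the medians against Col-0 were -0.29 in vtc1-1 and -0.18 in vtc2-1, with 8 and 16 of 69 above 0. The p of camera in limma was then 2.18e-09 and 0.00269 (0.241 and 0.535 with an estimated correlation), so that the values depend on that array. With an estimated correlation no p of camera given here was below 0.241, so the small ones depend on the preset correlation as well.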
